A study of Mus musculus with 10 samples.

How the data were processed

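Genomic DNA from 10 libraries of Abelson-transformed Lig4-deficient pre-B cells was analysed by linear-amplification-mediated high-throughput genome-wide translocation sequencing on the MiSeq platform, per the labels' protocols. The authors' deposited files list 1 translocation junction per row, with its position, strand, read sequence and bait and prey alignments, per the file headers. They hold no counts per region and no normalization. The labels name the standard pipeline of the assay, and the submitters' processing notes name bedtools and the builds mm10 and GRCm38.p2. All junctions in the files were used except 83 off chromosomes 1 to 19, X and Y. Gene positions came from the NCBI RefSeq table of GRCm38.p6, whose main chromosomes have the same coordinates as mm10.

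Groups and replicate numbers were taken from the labels, which name untreated replicate 1 as the control of etoposide replicate 1 and untreated replicate 2 as that of etoposide replicate 2. Nothing in the labels says that replicates came from separate cultures. P-values from limma and the permutation test therefore measure only the spread between libraries, which may be technical. Those from Fisher's exact test measure counting error alone and do not cover that spread. Read names placed the libraries in 4 sequencing runs: A (untreated and etoposide replicate 1), B (untreated replicate 2, IFN, DRB), C (etoposide replicate 2, IFN with etoposide, DRB with etoposide) and D (both AsiSI libraries). Run A had longer prey alignments, with medians of 233 and 266 bp against 62 to 73 bp elsewhere, and its untreated library had a higher prey share. Etoposide and its control share a run only in replicate 1, and the AsiSI libraries share none with the untreated ones.

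Prey junctions lay more than 1 Mb from the bait break. Antigen receptor loci were clusters of at least 10 annotated immunoglobulin or T-cell receptor segments with gaps of at most 1 Mb. Gene body and gene end shares were computed over prey outside chromosome 6. The gene table gives no strand, so the planned share within 5 kb of a transcription start was replaced by the share within 5 kb of either end of a protein-coding gene, and a junction in several genes went to the gene with the nearest end. No genome sequence was used here. The planned search for the CTCF motif within 1 kb of a junction was therefore replaced by a search of the prey part of the reads for the same motif, with antigen receptor loci left out. The motif written backwards contains a CpG and occurred in 0 reads of any library, so it served poorly as a control. AsiSI sites were replaced, as planned for this case, by 2-kb windows with at least 4 prey junctions over both AsiSI libraries and 0 in the other 8. For AsiSI against untreated, windows came from the DRB and AsiSI library alone, with at least 3 junctions there and 0 in the IFN, DRB and etoposide libraries, so that the AsiSI library did not choose its own windows.

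Groups of 2 were compared with the exact permutation test, which cannot go below 0.333 for 2 against 2. Single libraries were compared with Fisher's exact test, two-sided, and with odds ratios and ratios of rates with 95% intervals from a normal approximation on the log scale. For rates per junction near the bait, the intervals took the number near the bait as free of error, so they are too narrow. Identical positions were all counted in these rates. Exact Clopper-Pearson intervals and limits from 3 counts cover counting error only. Junctions per gene (body plus 2 kb) were fitted with limma 3.58.1 in R 4.3.3 with voom weights, library size set to prey junctions and at least 10 junctions over the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Other work used Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6. Recurrent 20-kb windows were tested against the Poisson rate with adjusted p under 0.01, as means over repeated random thinnings. The interferon list was set against 10000 random lists matched on junction count. The simulated fit of etoposide against untreated tested 239 genes and called 0 of 51 genes changed 4-fold, 9 of 90 changed 16-fold and 0 of 98 unchanged ones. In 100 simulations with no gene changed, drawn as Poisson counts at pooled gene rates, 1 made a call. These held no spread beyond counting error and no shift in the antigen receptor share. They therefore do not give the rate of false calls in the real libraries. The window test called 0 windows in data without clustering and all 10 in which clusters were placed.

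The lists, comparisons, tests and most alternatives were fixed before the data were examined. All members of the 10 lists were found in the gene table, some through older names. Genes were named by a rule: for etoposide the 10 with the most junctions, the 10 largest changes up and down past the threshold and the same way in both replicates, and up to 4 members of each list with the most junctions. For single libraries they were, among genes with at least 20 junctions, the 5 largest and 5 smallest ratios and up to 4 members of the interferon list. For AsiSI they were the 10 windows with the most junctions. Some genes that the rule picks are not reported here. Ifit2 was named after its values were seen. The counts with DRB in the 10 genes with the most etoposide junctions, the comparison of bait chromosome shares, junctions per 1000 near the bait and the DRB effect on gene body share with AsiSI were also added after seeing the data. Alternatives covered identical positions, the bait window, chromosome 6, antigen receptor loci, window sizes, gene models, scaling, low counts, pairing and left-out replicates.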

Results

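Translocation junctions were mapped in Abelson-transformed pre-B cells from C57BL/6 mice that lack Lig4, the ligase of classical end joining. The cells were arrested in G1 with imatinib, the inhibitor of the transforming Abl kinase. High-throughput genome-wide translocation sequencing starts from 1 fixed DNA break, the bait, and reads the sequence that each bait end has joined, the prey. A doxycycline-induced zinc-finger nuclease made the bait break on chromosome 6 (mm10), between the T-cell receptor beta segments Trbc2 (41546730 to 41548181) and Trbv31 (41557693 to 41558371). Etoposide, which traps topoisomerase II on cut DNA, was given at 50 µM for 2.5 h and followed by 12 h of recovery. There were 10 libraries in 8 groups: untreated (n = 2), etoposide (n = 2), and 1 library each of IFN, IFN with etoposide, DRB, DRB with etoposide, AsiSI and DRB with AsiSI. DRB inhibits transcription, AsiSI is a restriction enzyme induced in place of etoposide, and the labels give IFN only as an abbreviation under drugs that affect transcription. DRB was given as a pretreatment of 2 h. The AsiSI libraries alone received tamoxifen, at 1 µM and 20 h after doxycycline, so they differ from the untreated libraries in tamoxifen as well. Each library held between 2044 and 13425 junctions, 68433 in all. Prey junctions, defined as those more than 1 Mb from the bait, numbered 915 and 1055 in the untreated libraries, 10521 and 3721 with etoposide, 648 with IFN, 3623 with IFN and etoposide, 489 with DRB, 463 with DRB and etoposide, 2231 with AsiSI and 2919 with DRB and AsiSI. Groups of 1 library have no replicate check, and tests on them compare libraries and not conditions. Shares of single libraries carry exact 95% binomial intervals that cover counting error only.

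The first comparison asked whether topoisomerase II breaks join the bait. Within each replicate number, etoposide raised joining to the rest of the genome by about an order of magnitude, while joining to the immunoglobulin kappa locus, which RAG cuts in arrested pre-B cells, did not rise. Per 1000 junctions within 1 Mb of the bait, prey outside antigen receptor loci numbered 601 and 70.2 in untreated replicates 1 and 2 and 8605 and 821 in etoposide replicates 1 and 2. That was 14.3-fold higher in replicate 1 (95% interval 13.2 to 15.5), whose libraries share a sequencing run, and 11.7-fold higher in replicate 2 (10.5 to 13.0), whose libraries do not. These intervals take the counts near the bait as free of error and are therefore too narrow. Repeated positions, 490 in untreated and 638 in etoposide replicate 1, were all counted, which could move these ratios. The untreated libraries themselves differed 8.57-fold, and etoposide replicate 2 was only 1.37-fold above untreated replicate 1, so the size of the rise depends on each library being set against the control that the labels name. Antigen receptor prey per 1000 junctions near the bait was 213 and 130 without and 177 and 106 with etoposide. The prey share of all junctions was 68.9% ± 29.5 (SD, n = 2) with etoposide and 30.8% ± 19.9 (SD, n = 2) without. The difference of 38.2 percentage points was 44.9 within replicate 1 and 31.4 within replicate 2, and it ranged from 17.3 without etoposide replicate 1 to 59.0 without etoposide replicate 2. The replicates differed about as much as the groups, and the exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow.

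**Figure D1:**
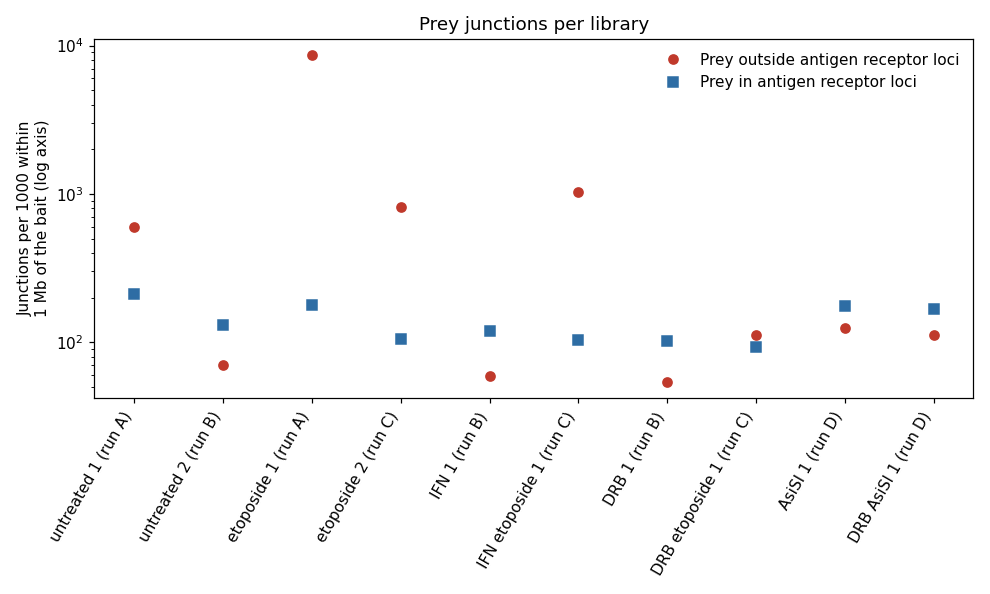
Prey junctions per 1000 junctions within 1 Mb of the bait, on a log axis, for each of the 10 libraries with its sequencing run (A to D). Circles show prey outside antigen receptor loci, which reach 8605 in etoposide replicate 1 and 113 with DRB and etoposide, and squares show prey in antigen receptor loci, which lie between 92.7 and 213.

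Without etoposide, antigen receptor loci took most prey in 5 of the 6 libraries. They held 26.1% (95% interval 23.3 to 29.1) and 64.9% (62.0 to 67.8) of prey in untreated replicates 1 and 2, 66.8% (63.0 to 70.4) with IFN, 65.4% (61.0 to 69.7) with DRB, 58.2% (56.1 to 60.3) with AsiSI and 59.8% (58.0 to 61.6) with DRB and AsiSI. Their share was 2.02% (1.76 to 2.30) and 11.4% (10.4 to 12.5) in etoposide replicates 1 and 2, 9.25% (8.32 to 10.2) with IFN and etoposide and 45.1% (40.5 to 49.8) with DRB and etoposide. Nearly all of these junctions lay in the kappa locus (chromosome 6, 67555636 to 70726754), with 237 and 685 in the untreated libraries. The immunoglobulin heavy chain cluster (chromosome 12, 113256204 to 116009954) held 0 in both untreated libraries and 2 in each etoposide library. The T-cell receptor alpha and delta cluster (chromosome 14, 52427967 to 54224198) held at most 11 junctions in any library. The lower share with etoposide (6.72% ± 6.65 against 45.5% ± 27.4, SD, n = 2 each) goes with a larger number of other prey junctions. Off the bait chromosome the difference, etoposide minus untreated, was -0.00324 percentage points.

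Etoposide junctions lay in genes. Outside chromosome 6, 67.1% (65.9 to 68.2) and 67.7% (65.6 to 69.7) of prey in etoposide replicates 1 and 2 fell inside protein-coding gene bodies, against 39.0% (35.1 to 43.0) and 44.5% (38.2 to 51.0) in the untreated libraries. Gene bodies cover 38.6% of the annotated length, so untreated replicate 1 lay at that share and replicate 2 above it, with an interval that includes it. A single 20-kb window on chromosome 2, which starts at 98660000, held 80 junctions in untreated replicate 1 and 0 in replicate 2. The match in replicate 1 may therefore rest on that window. The group means were 67.4% ± 0.443 and 41.8% ± 3.92 (SD, n = 2 each), and the difference of 25.6 percentage points was 28.1 within replicate 1 and 23.2 within replicate 2. It exceeded the spread between replicates, and the exact permutation p was 0.333, the smallest possible. With the windows recurrent without etoposide left out it was 23.1 percentage points. Within 5 kb of either end of a gene lay 29.5% (28.3 to 30.6) and 30.2% (28.2 to 32.2) of etoposide prey and 14.6% (11.9 to 17.6) and 19.8% (15.1 to 25.4) of untreated prey, where such regions cover 12.3% of the length. These group means were 29.8% ± 0.497 and 17.2% ± 3.73 (SD, n = 2 each; exact permutation p = 0.333). With prey on the bait chromosome included, the gene body difference was 40.3 and the gene end difference 19.2 percentage points. That setting adds the kappa junctions, and V and J segments do not count as protein-coding genes. Antigen receptor loci held 26.1% and 64.9% of untreated prey but 2.02% and 11.4% of etoposide prey. The larger differences therefore do not by themselves show more joining to genes on chromosome 6.

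**Figure D2:**
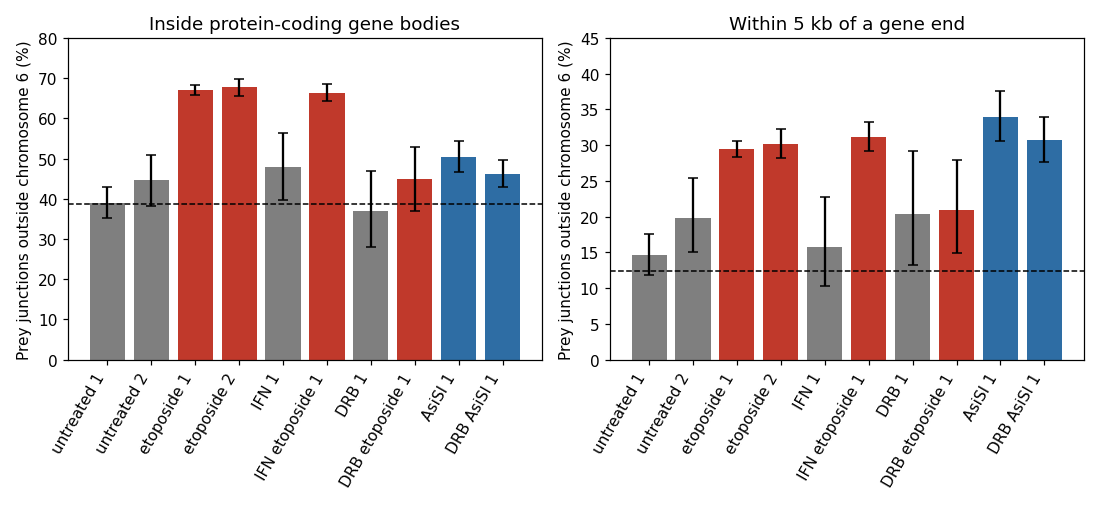
Share of prey junctions outside chromosome 6, in percent, inside protein-coding gene bodies (left) and within 5 kb of a gene end (right) for each library, with exact 95% binomial intervals as error bars. Dashed lines mark the share of annotated length, 38.6% and 12.3%. Red bars are libraries with etoposide, blue bars with AsiSI and grey bars with neither. The DRB with etoposide library, at 44.8%, stands below the other libraries with etoposide in the left panel.

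The gene lists differed in junction density, which no test compared between lists. In etoposide prey outside chromosome 6, B-lineage genes carried 289 junctions per 100000 prey per Mb, averaged over both libraries, immediate-early genes 491, highly expressed housekeeping genes 244, p53 target genes 242, canonical histone genes 217 (59.5 from 1 junction and 374 from 2) and recurrent leukaemia translocation genes 185. Genes of the transcription machinery and small nuclear RNA neighbours carried 147 and interferon-stimulated genes 84.5. All protein-coding genes together carried 63.6, genes of other blood lineages 26.1 from 3 junctions, and long neural genes 6.90 and 9.10 in the 2 libraries. In the untreated libraries B-lineage genes carried 214 and 89.1 (from 6 junctions and 1) and long neural genes 20.9 and 52.3. Long neural genes, which span 69.7 Mb, took 31 of 6443 and 13 of 2049 etoposide prey junctions and 9 of 618 and 9 of 247 untreated ones. Their share of prey was lower with etoposide in both replicates and passed in replicate 2 only (Fisher's exact test, two-sided, adjusted p = 0.0657 in replicate 1 and 0.00472 in replicate 2, over 20 tests). Per 1000 junctions near the bait their junctions rose from 8.01 to 25.9 in replicate 1 and from 1.71 to 3.24 in replicate 2, so the lower share came with a larger rise of other prey. The share was higher in both etoposide libraries than in both untreated ones for 5 of the 10 lists, B-lineage, canonical histone, leukaemia translocation, p53 target and transcription machinery genes. This order rests on 0 to 6 junctions per untreated library. For histone and p53 genes, with 0, the etoposide shares lay below the untreated limits of 0.485% and 1.21%, so depth alone could set it. No other list passed the adjusted Fisher test. B-lineage genes took 1.31% ± 0.145 of etoposide prey and 0.688% ± 0.400 of untreated prey (SD, n = 2 each). Counted on all chromosomes, the transcription factor Foxp1 led that list, with 121 junctions in the 2 etoposide libraries and 30 in the untreated ones. Next came the adaptor Blnk (10 etoposide junctions) and the transcription factors Ebf1 (10) and Pax5 (8), each with 0 in the untreated libraries. Among immediate-early genes Tnfaip3 had 5, Cd69 3 and Btg1 and Btg2 2 each. Among housekeeping genes Hnrnpa2b1 had 6, Actb 3, Eef2 2 and Actg1 1, and among p53 targets Xpc had 6, Bax 3 and Plk3 2. Among transcription machinery genes the cohesin subunit genes Stag1 and Smc1a had 5 and 3 and Cdk13 4. The histone genes H2ac18, H2aw, H3c1 and H4f16 had 1 each. Among the neural genes Cntnap2 had 8, Ank2 6 and Ctnna2 4, and among genes of other blood lineages Tcf7 had 2 and Cd8b1 1.

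**Figure D3:**
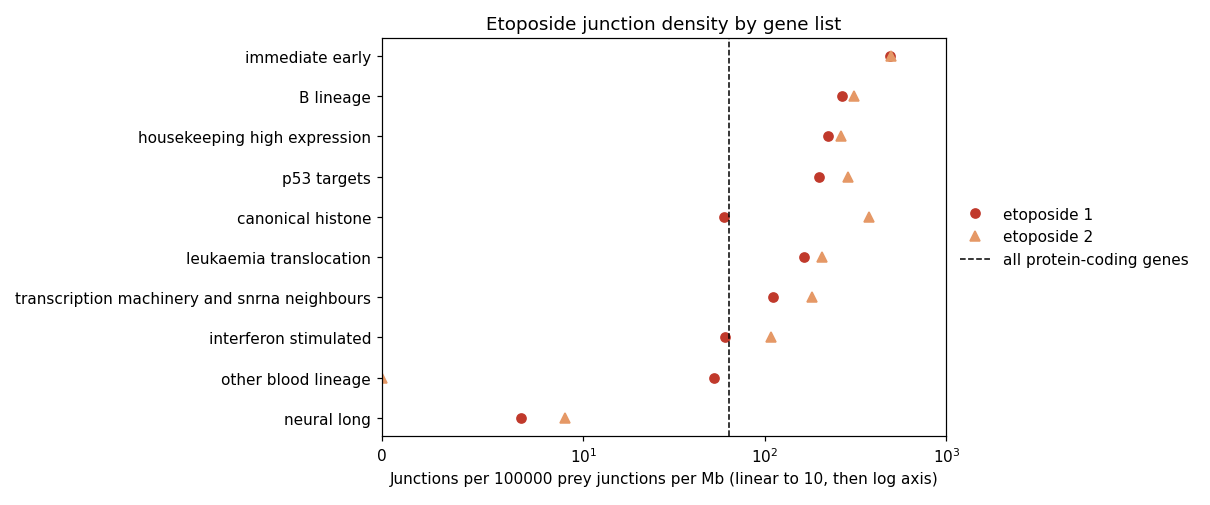
Etoposide junctions per 100000 prey junctions per Mb of gene (body plus 5 kb, outside chromosome 6) for the 10 gene lists, on an axis that is linear to 10 and logarithmic above. Circles show etoposide replicate 1, triangles replicate 2, and the dashed line all protein-coding genes, at 63.6. Long neural genes lie at 6.90 and 9.10 and B-lineage genes at 266 and 311.

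The bait chromosome supplied the most frequently joined genes. Outside antigen receptor loci, chromosome 6 held 37.6% (36.7 to 38.6) and 37.9% (36.3 to 39.6) of etoposide prey, although it makes up 5.51% of the summed chromosome length. It held 8.88% (6.84 to 11.3) and 33.2% (28.5 to 38.3) of untreated prey. The difference was 28.7 percentage points within replicate 1 and 4.68 within replicate 2, and 4.52 without untreated replicate 1. Without etoposide the share was also 32.1% with IFN, 36.1% with DRB, 25.1% with AsiSI and 28.4% with DRB and AsiSI. Untreated replicate 1 was the lowest of all libraries, so the 28.7 points rest on it, and joining to chromosome 6 was frequent without etoposide. The 10 genes with the most etoposide junctions were all on chromosome 6. Foxp1, a transcription factor gene of the B lineage (98925342 to 99522746), had 83 and 38 junctions in etoposide replicates 1 and 2, and Exoc4, which encodes an exocyst subunit, had 64 and 22. Iqsec1 had 47 and 12, the kinase gene Hipk2 37 and 15, the calcium channel gene Itpr2 39 and 12, Fam3c 38 and 11, the kinase gene Braf 21 and 20, the leukaemia fusion gene Etv6 32 and 7, Ube2h 34 and 5, and Vgll4 27 and 11. The untreated libraries held 30 junctions in Foxp1, 3 in Exoc4, 1 in Iqsec1 and 0 in the other 7. Foxp1 and Etv6 led the leukaemia translocation list, followed by Ccnd2 (12 junctions) and Cux1 (10).

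In a limma fit with voom weights over the 121 genes with at least 10 junctions, of which 111 were on chromosome 6, 68 genes rose and 1 fell with etoposide at an adjusted p under 0.05. All 68 had 0 junctions in both untreated libraries, as did 97 of the 121 genes fitted. The etoposide libraries held 10521 and 3721 prey junctions against 915 and 1055, so genes passed the filter mostly through etoposide. The largest fitted log2 fold changes were those of Hipk2 (2.93 ± 0.50 SE, limma adjusted p = 0.0276), Braf (2.82 ± 0.57, limma adjusted p = 0.0276), Itpr2 (2.79 ± 0.49) and Fam3c (2.71 ± 0.49). Itpr1, Frmd4b and Luc7l2 were also among the 10 largest, with 32, 29 and 18 etoposide junctions. Per prey junction, and against the limit of 3 junctions over both untreated libraries, Hipk2 was at least 2.40-fold higher, Itpr2 at least 2.35-fold and Braf at least 1.89-fold. These bounds hold on that scale alone. Antigen receptor loci took 26.1% and 64.9% of untreated prey but 2.02% and 11.4% of etoposide prey, so per prey junction outside them the bounds would be lower. The gene that fell was Parp11 (log2 change of -1.15 ± 0.22 SE, limma adjusted p = 0.0276), with 8 etoposide and 2 untreated junctions. The calls depend on how libraries are scaled and on the few untreated junctions. The count was 97 without voom weights and 0 with Fisher's exact test on pooled junctions, and it was at most 1 when any of the 4 libraries was left out. With library sizes taken from prey outside antigen receptor loci it was 0, and the median log2 fold change over all 121 genes fell from 1.06 to 0.19. Per junction near the bait all 121 genes lay above 0, with a median of 3.50 and 0 calls. Of the fixed lists, 3 B-lineage genes, 5 leukaemia translocation genes and 1 interferon-stimulated gene, Parp11, entered the fit, and the first 2 lists moved up on balance (limma fry, FDR 0.0413 and 0.0313). Genes passed the filter mostly through etoposide, and 97 of the 121 lay above 0, so fry was likely to give this for most lists and says nothing about these. Neither list differed from the other genes (limma camera, FDR 0.941 each, and 0.9496 each with an estimated correlation). Adjusted over the list alone, 0 and 1 members passed.

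At equal depth, prey clustered in more windows of 20 kb in untreated than in etoposide cells. With every library thinned to 915 prey junctions, 28.0 and 44.9 windows exceeded the Poisson rate in the untreated libraries, and 6.45 and 15.4 did so with etoposide. On average 21.5 of these windows were shared by the untreated libraries and 0.95 by the etoposide libraries. In windows of 100 kb the difference was gone, with 21.0 and 34.3 untreated and 25.55 and 27.95 with etoposide. At 370 junctions per library the mean number of windows was 16.4 untreated and 3.23 with etoposide, and with antigen receptor loci left out at that depth 6.88 and 0.5. Windows shared by the untreated libraries at that depth numbered 8.8 with these loci and 0.95 without them, so most lay in these loci. The etoposide libraries shared 0.2 and 0. Without thinning the order turned, with 28 and 52 windows in the untreated libraries and 332 and 124 with etoposide. The core motif of CTCF, the protein that anchors chromatin loops, was sought within the prey reads. It occurred in 22 of 6432 and 2 of 2046 etoposide prey reads outside chromosome 6 and in 1 of 616 and 0 of 247 untreated ones. Per Mb of prey sequence this was 14.1 (9.51 to 20.1) over all 4 libraries with etoposide and 8.77 (1.81 to 25.6) over the 6 without, so no difference was detectable at this depth.

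The next comparison asked whether transcription was needed for etoposide breaks to join the bait. With DRB, most of the etoposide effect was lost. Prey outside antigen receptor loci numbered 113 per 1000 junctions near the bait with DRB and etoposide, a ratio of 0.137 (95% interval 0.121 to 0.156) to etoposide replicate 2, which was sequenced in the same run. Etoposide raised such prey 2.09-fold (1.72 to 2.54) over the DRB library, 17.3-fold (15.0 to 19.8) over the IFN library and 11.7-fold between the replicate 2 libraries. The prey share was 17.0% (15.6 to 18.5) with DRB and etoposide and 13.5% (12.4 to 14.6) with DRB alone. The difference was -31.1 percentage points to etoposide replicate 2 and -72.7 to etoposide replicate 1, which themselves differed by 41.7. Of the 10 genes with the most etoposide junctions, Foxp1 had 10 with DRB and etoposide, as many as with DRB alone, Exoc4 and Iqsec1 had 1 each, and Hipk2, Itpr2, Fam3c, Braf, Etv6, Ube2h and Vgll4 had 0. Per junction near the bait, etoposide replicate 2 predicted 21.4 for Foxp1, 12.4 for Exoc4, 11.2 for Braf, 8.43 for Hipk2 and 6.74 for Itpr2. The count was lower in 7 of the 10 at an adjusted p under 0.05 (Fisher's exact test between libraries, for Braf adjusted p = 0.00205, for Exoc4 0.00361), in genes chosen for their etoposide counts, and not in Iqsec1, Etv6 and Ube2h. Per prey junction, a scale that takes the overall loss as given, the predictions were 3.93 for Foxp1, 2.80 for Exoc4 and 1.92 or less for the others. Frmd4b had 2, and Mkln1 and Atg7 1 each.

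The junctions that remained with DRB lay less often in genes. The gene body share was 44.8% (37.0 to 52.8), a difference of -22.3 percentage points to etoposide replicate 1 and -22.9 to replicate 2, which differed from each other by 0.627 (Fisher's exact test between libraries, two-sided, p = 1.01e-08 and 8.69e-09). The gene end share was 20.9% (14.9 to 27.9), with differences of -8.60 and -9.30 percentage points to the etoposide libraries (Fisher's exact test, p = 0.0183 and 0.0123), whose own gap was 0.703. Against DRB alone, at 37.0% (27.9 to 46.9) and 20.4% (13.2 to 29.2), neither share differed detectably (Fisher's exact test, p = 0.211 and 1.0).

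The IFN libraries asked whether raising the transcription of chosen genes draws etoposide breaks to them. Interferon-stimulated genes took 1.10% of prey with IFN and etoposide (40 of 3623, 95% interval 0.790 to 1.5), against 0.266% (28 of 10521, 0.177 to 0.384) and 0.430% (16 of 3721, 0.246 to 0.697) in the etoposide libraries. The odds ratio was 4.16 (2.57 to 6.73) to etoposide replicate 1 and 2.54 (1.43 to 4.51) to replicate 2, which shares the run (Fisher's exact test between libraries, two-sided, p = 8.24e-09 and 0.0011). The list's log2 ratio of 1.84 exceeded that of all 10000 random lists matched on junction count, whose median was -0.06. Usp18, which encodes the deISGylase that dampens interferon signalling, had 11 junctions within 5 kb with IFN and etoposide and 2 in each etoposide library. Herc6, an ISG15 ligase gene, had 5 against 1 and 2, and Ifit2 had 3 against 0 and 0. Tmem140 had 3 against 4 and 2, and Parp11 4 against 6 and 2, where etoposide replicate 1 had the most prey. Per prey junction, the Parp11 count was 1.97 times that of the etoposide libraries together. All of these but Ifit2 lie on chromosome 6. Without that chromosome the difference was 0.444 percentage points, and the test against etoposide replicate 2 no longer passed (Fisher's exact test, p = 0.147). With IFN alone the list had 1 of 648 prey junctions, and in the untreated libraries 1 of 915 and 2 of 1055.

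IFN left the overall distribution of etoposide prey close to that of etoposide alone. The gene body share was 66.4% (64.3 to 68.5), with differences of -0.681 and -1.31 percentage points to the etoposide libraries. The prey share of 52.98% (51.8 to 54.2) differed by 4.86 percentage points from etoposide replicate 2 and by -36.8 from replicate 1, so its direction depended on the library. Of the 49 genes with at least 20 junctions, Etnk1 (16 junctions, 2.73 times the etoposide rate), Nrf1 (8, 2.62 times) and Zc3hav1 (12, 2.36 times), which encodes an antiviral RNA-binding protein, had the largest ratios with Tmem178b and Atp2b2. Against etoposide replicate 2 alone, the library of the same run, Zc3hav1 stood at 4.11 times, Tmem178b at 5.14 and Atp2b2 at 3.59. Vgll4 (2 junctions), Aebp2 (1) and Mkln1 (1) had the smallest, each at 0.207 times the etoposide rate (0.187, 0.342 and 0.342 against replicate 2 alone), followed by Lrmp and Tbxas1.

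AsiSI cuts fixed sites, so its libraries hold breaks that do not come from topoisomerase II. These libraries differed from the others in the share of kappa prey at J segments, 0.233% and 0.116% against 3.48% to 7.21%, and the labels do not say whether they came from the same clone. The rule for AsiSI windows chose 19 windows of 2 kb, which held 92 junctions with AsiSI and 90 with DRB and AsiSI. It required at least 4 over both libraries and 0 in the other 8, so the absence elsewhere is no result. The rule also leaves out windows joined in any other library. Zc3hav1, which is not among the windows, had 16 junctions with AsiSI and 8 with DRB and AsiSI, and 17 and 3 in the etoposide libraries. Of the 19 windows, 15 had their median junction within 5 kb of a protein-coding gene end. The most joined lay in Syde2 (chromosome 3, 145988000 to 145989999), with 34 junctions with AsiSI and 25 with DRB and AsiSI. Windows at Rcor1 had 8 and 8 (chromosome 12), at Mex3a 7 and 5 (chromosome 3), Klf7 3 and 7 (chromosome 1), Romo1 6 and 4 (chromosome 2) and Alas1 5 and 2 (chromosome 9). Further windows with many junctions lay in Dyrk3 and Fam160b1 and nearest to Olfr132. In windows chosen from the DRB and AsiSI library alone, the AsiSI library had 76 of 2231 prey junctions (3.41%, 95% interval 2.69 to 4.25). The untreated libraries had 0 of 915 and 0 of 1055 (limits of 0.328% and 0.284% from 3 counts; Fisher's exact test between libraries, p = 3.88e-12 and 1.74e-13). The gene end share was 34.0% (30.5 to 37.6) with AsiSI, above both untreated libraries, and the gene body share 50.5% (46.7 to 54.2).

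In the AsiSI libraries DRB had a smaller effect than in the etoposide libraries, and the difference at AsiSI windows depended on the setting. The 19 windows took 4.12% (3.34 to 5.03) of prey with AsiSI and 3.08% (2.49 to 3.78) with DRB and AsiSI (Fisher's exact test between libraries, p = 0.0478), a difference that did not pass with identical positions counted once (p = 0.0772), outside chromosome 6 (p = 0.105) or in windows of 10 kb (p = 0.0646). It passed in windows of 500 bp, at -1.37 percentage points (Fisher's exact test, p = 0.0132), and with a bait window of 5 Mb (p = 0.0477). Set against junctions near the bait, the windows held 92 beside 7431 with AsiSI and 90 beside 10485 with DRB and AsiSI. That rate was lower with DRB and was not tested. Prey outside antigen receptor loci per 1000 junctions near the bait stood at 0.892 times (0.818 to 0.972) the level without DRB. Most of this prey lay outside the windows. The gene body share was 46.3% (42.9 to 49.7) with DRB and AsiSI, a difference of -4.23 percentage points to AsiSI alone (Fisher's exact test, p = 0.104). It passed with the bait chromosome included, at -3.12 (Fisher's exact test, p = 0.00655), and with all gene biotypes, at -5.43 (Fisher's exact test, p = 0.0316).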

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

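The tests of library quality, of joining in general, of dilution, of a single gene and of sequencing runs were chosen only after the results they measure were seen. Those of repeated positions and of gene bodies were written before their outcome was seen.

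The DRB effect differed between the etoposide and AsiSI libraries. These libraries also differed in tamoxifen and in the timing of break induction. DRB lowered the odds that a junction lay outside antigen receptor loci and away from the bait to 0.137 (95% interval 0.120 to 0.158) with etoposide, in replicate 2's run, and to 0.892 (0.814 to 0.977) with AsiSI. The ratio of these odds ratios was 0.154 (0.131 to 0.182), tested on counting error with 1 library each. A small or poorly amplified library would lower every class of prey, but antigen receptor junctions per 1000 near the bait stood at 0.875 times (0.742 to 1.03) those of etoposide replicate 2. A loss of joining at any break as large as with etoposide is argued against by the ratio of 0.892 (0.818 to 0.972) for other prey in the AsiSI libraries. Most of that prey lay outside the AsiSI windows, which held 92 of 932 junctions with AsiSI and 90 of 1173 with DRB and AsiSI. The ratio therefore says little about AsiSI breaks themselves. At the AsiSI windows the DRB odds ratio was 0.740 (0.551 to 0.994), and without etoposide or AsiSI other prey with DRB stood at 0.767 times (0.639 to 0.920) untreated replicate 2, so a smaller loss stays open, as does another clone for the AsiSI libraries. The lower gene body share with DRB may come in part from dilution, since a mix of DRB background and etoposide-like junctions would give 52.9%, just above the interval of 37.0 to 52.8 around the observed 44.8%, so this stays open. A lower number of etoposide breaks when transcription is blocked remains a hypothesis, as does any other effect of DRB on etoposide action that these libraries do not measure.

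The share of interferon-stimulated genes with IFN and etoposide could rest on a single gene, but without Usp18 the share was 0.800% against 0.247% and 0.376%, and the larger of the 2 Fisher p-values was 0.0210. A difference between runs is argued against by the odds ratio of 2.54 (1.43 to 4.51) within the run. Chance differences between cultures cannot be measured with 1 library. That stimulated genes became more exposed to etoposide breaks is a hypothesis.

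The overlap between bait and prey alignments, a column not used in the comparisons, marks microhomology at the junction. Outside antigen receptor loci, 73.2% ± 0.930 of etoposide prey overlapped by 2 bp or more, against 48.9% ± 9.56 of untreated prey (SD, n = 2 each). Values were 75.6% with IFN and etoposide, 59.4% with DRB and etoposide, 53.5% with IFN, 58.0% with DRB, 62.1% with AsiSI and 59.5% with DRB and AsiSI. Within runs etoposide lay above its untreated library in replicate 1 and above the DRB and etoposide library in replicate 2's run by at least 13.1 percentage points, with intervals apart, which argues against the run as the cause. With repeated positions and 3 windows joined often without etoposide left out the difference was 25.4 points, and outside gene bodies 22.6 points, so neither accounts for it. A larger share of spurious junctions among the few prey of untreated cells was not tested and could also give this difference.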

How the results depend on the processing

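The leaving out of 3 windows recurrent without etoposide, the settings without antigen receptor loci for prey shares, lists and windows, and the library sizes from prey outside those loci and from junctions near the bait were chosen after the data were seen. Etoposide against untreated kept its direction under every alternative run for the prey share, gene end share and gene body share. The antigen receptor share kept its direction except outside chromosome 6, where no difference remained. Leaving out 1 library each gave 17.3 to 59.0 percentage points for the prey share, 9.97 to 15.2 for the gene end share, 22.8 to 28.4 for the gene body share and 4.52 to 28.9 for the bait chromosome share. Including the bait chromosome, and with it the kappa junctions, moved the gene end difference from 12.6 to 19.2 and the gene body difference from 25.6 to 40.3. Leaving that chromosome out moved the antigen receptor difference from -38.8 to -0.00324. Windows of 2 and 10 kb moved the gene end difference to 8.51 and 18.3. Lists higher in both etoposide libraries numbered 5, or 7 with the bait chromosome.

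The 69 gene calls became 14 with the IFN pair and the replicate block added and 14 with the IFN and DRB pairs and the block added, 0 with all 10 libraries, 0 at a minimum of 4 junctions and 24 at 20, 13 with library sizes from all junctions, 5 with median-ratio scaling (which rests on 3 genes), 24 without flanks, 0 with gene ends alone, 0 with Fisher's exact test, 0 with library sizes from prey outside antigen receptor loci and 0 from junctions near the bait. Leaving out 1 library gave 0 to 1, where a lone library is assumed to vary like the other group. The cause of these changes was not tested, apart from fewer genes or libraries where the setting removes them. The fit and the group tests did not pair the replicate numbers, while ratios per junction near the bait follow the controls that the labels name. The replicate numbers share a correlation of deviations of only 0.0431. Of the 121 genes, 97 had 0 junctions in both untreated libraries and hence the same untreated deviation, so this correlation cannot tell whether the replicates are paired. With the replicate block the count was 65 (63 up, 2 down), of which 61 were among the 69, and the paired differences of the prey, gene end and gene body shares were 38.2, 12.6 and 25.6, which changed no call on those shares. The difference in recurrent windows, -25.5 and the same as a mean within replicate numbers under the block, was -0.900 in 100-kb windows, -36.3 at a threshold of 0.05 and -13.2 at 370 junctions per library, chosen last, and -6.38 at that depth without antigen receptor loci. It turned to 188 without thinning, where depth differs, and ranged from -39.5 to -18.5 with 1 library left out.

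Against etoposide, DRB gave lower prey, gene body and gene end shares under all alternatives, from -72.7 to -31.1, -22.9 to -22.3 and -9.30 to -8.60 with 1 etoposide library left out. The IFN prey difference of -16.0 turned to 4.86 without etoposide replicate 1 and was -36.8 without replicate 2. The interferon gene difference of 0.756 ran from 0.674 to 0.838 with 1 library left out and was 0.444 outside chromosome 6, where it no longer passed. AsiSI against untreated passed under every alternative, at 3.41 with either untreated library left out. The DRB difference at AsiSI windows was -0.921 with identical positions counted once, -2.60 outside chromosome 6 and -1.02 in 10-kb windows, none of which passed, and -1.37 in 500-bp windows, which passed. The gene body difference between the AsiSI libraries was -3.12 with the bait chromosome and -5.43 with all biotypes, both of which passed. The CTCF difference per Mb of 8.50 ran from 5.29 to 11.7 with 1 library left out and was 16.1 with the IFN pair added. The transcription-start settings, including the gene region of 5 kb around a start, and all settings for the CTCF motif near junctions were not run as planned, since strand and genome sequence were not used here, and gene ends took the place of starts. Depth limits the untreated, IFN and DRB libraries most, with 108 to 618 prey junctions outside chromosome 6.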

Other observations

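Within the kappa locus, prey junctions were spread over the V genes. Of 162 annotated V segments, 118 had at least 1 junction within 500 bp over all libraries, and V segments took 56.1% and 51.2% of kappa prey in the untreated libraries. Igkv6-32 had 382 junctions over all libraries, of which 102 with AsiSI and 124 with DRB and AsiSI, and 7 and 45 in the untreated libraries. The 5 J segments (chromosome 6, 70722562 to 70723923) took 7.17% and 4.23% of kappa prey in the untreated libraries and between 3.48% and 7.21% in the other etoposide, IFN and DRB libraries. They took 0.233% (3 of 1288) with AsiSI and 0.116% (2 of 1730) with DRB and AsiSI. Igkv11-125 had 46 of 685 kappa junctions in untreated replicate 2 and 10 of 1288 with AsiSI.

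Foxp1 was also joined without etoposide. Counted in its annotated body without flanks, where etoposide replicate 2 had 37, it held 27 junctions in untreated replicate 2, 14 with IFN, 10 with DRB, 23 with AsiSI and 29 with DRB and AsiSI. Per 1000 junctions near the bait this was 5.12, 3.86, 3.18, 3.10 and 2.77, and 9.22 in etoposide replicate 2. As a share of prey outside antigen receptor loci, Foxp1 stood at 7.30% in untreated and 1.12% in etoposide replicate 2, and at 0.444% (3 junctions) in untreated and 0.805% in etoposide replicate 1. Per 1000 junctions near the bait it stood at 2.67 and 69.3 in replicate 1.

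Outside chromosome 6, the genes with the most etoposide junctions, chosen after their values were seen, were Rere (13), Gse1 (12), Arid1b (11), Mtss1 (11) and Trio (11), each with 0 in the untreated libraries. A 20-kb window on chromosome 2 that starts at 98660000 held 80 junctions in untreated replicate 1, 59 in etoposide replicate 1 and 0 in untreated replicate 2. A window on chromosome 6 that starts at 120600000 held 18 and 21 junctions in the AsiSI libraries and between 0 and 8 in each of the others.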
